A study of Mus musculus with 6 samples.

How the data were processed

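Total RNA of mouse hippocampus was measured on 6 one-colour Affymetrix mouse arrays, 3 from wild-type mice and 3 from mice lacking inhibitor-1, the protein phosphatase 1 inhibitor encoded by Ppp1r1a. The labels give the genotype, the tissue and a replicate number, and say nothing on sex, age, strain, the targeting construct or whether each array came from a separate animal. P-values therefore measure the spread between these samples, which may be technical. The deposited values are probe set intensity values on a linear scale, and the software that made them is not given in the sources used here. Every value lay above 0, and the mean after leaving out 2% of the values at each end was 2500 on all 6 arrays, so the deposited table had been scaled to one level before it was analysed here.

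The table held 45101 probe sets. The platform annotation gave 1 gene symbol for 34958 of them, several for 932 and none for 9211; of those with 1 symbol, 34754 were found by gene ID in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols were changed by it. That table was used only for names, chromosomes and the order of genes. No gene is named from a probe set with several symbols.

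Values were transformed as log2(intensity + 16) and kept on the deposited scale, so fold changes are on that scale and understate changes of dim probe sets. The 64 control probe sets and the 40% of probe sets with the lowest mean over all arrays were left out, which left 26999. The groups were compared with limma 3.58.1 in R 4.3.3 (a linear model with group as its only term, empirical Bayes with an intensity trend, two-sided), and a Benjamini-Hochberg adjusted p under 0.05 was the threshold. For tests of gene lists, each of 12493 genes was represented by its probe set with the highest mean. Gene lists were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 30 lists. The 25 measured genes on each side of Ppp1r1a were compared with all other genes by Fisher's exact test of the share at an unadjusted p under 0.01.

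The design, the 30 gene lists and the rule for named genes were fixed before the data were examined. The rule names Ppp1r1a, the 12 genes higher and the 12 genes lower with the smallest p (filled, where too few passed, from genes whose 3 knockout values all lay on one side of the 3 wild-type values), members of a list that passed over that list alone, the 2 members of smallest p of other lists that were called, and single markers of other cell types that show what an array holds. The alternatives were other pseudocounts, filters, scalings and variance models, array weights, the replicate number as a block, leaving out each array in turn, the mean of a gene's probe sets, an estimated correlation, and 10 or 50 neighbouring genes. Alternatives chosen after seeing the data were a pseudocount of 256, a neighbour threshold of 0.05, 100 neighbouring genes, leaving out replicate 1 of both groups, and the choroid plexus marker level as a covariate.

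The fit was tested on simulated values for the knockout against wild-type comparison over 26999 probe sets. Of the changed probe sets it recovered 32.8% of 67 at a log2 change of 0.5, 77.6% of 67 at 1 and 97.0% of 66 at 2, with 11 false calls. The simulated noise was independent between probe sets. The Benjamini-Hochberg threshold is more lenient where many probe sets change, and only 3 passed in the real data. These rates therefore do not give the sensitivity of the real comparison, which may be lower. The number of arrays limits the precision. No detection calls were used here.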

Results

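Hippocampal RNA of 3 wild-type and 3 inhibitor-1 knockout mouse samples was measured on 1 array each. The comparison asks which transcripts differ in the hippocampus when inhibitor-1, which restrains protein phosphatase 1 when phosphorylated by protein kinase A, is missing. The 3' over 5' signal ratio of beta-actin was 1.24 to 1.30 in wild type and 1.18 to 1.21 in knockout, without overlap, and that of Gapdh was 0.809 to 0.880 in wild type and 0.821 to 0.829 in knockout. An array's mean correlation with the others of its own group was 0.963 to 0.974, and with the other group 0.968 to 0.972. Knockout replicate 1 had the lowest correlation with its own group, 0.963 against 0.971 with wild type. Xist, the X-inactivation transcript, was bright on all 6 arrays, at log2 values of 14.4 to 15.3 for its brightest probe set. The 9 Y-linked probe sets stayed at or below 8.23, under the level of 8.44 that 40% of probe sets lie below.

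Ppp1r1a, the targeted gene, was the transcript with the lowest p. Its only probe set, 1422605_at, had an intensity of 9258 ± 1002 (SD, n = 3) in wild type and 289.4 ± 51.5 (SD, n = 3) in knockout. It fell by 4.93 on the log2 scale (SE 0.18, limma adjusted p = 3.58e-07). With knockout values set no lower than the log2 level of 8.44 that 40% of probe sets lie below, it was at least 26.2-fold lower, and no detection calls were used here. The knockout values lay at the 30.2 to 36.5 percentile of their arrays and the wild-type values at the 90.2 to 92.2 percentile. Where this probe set lies relative to the targeted part of the gene is not given in the sources used here.

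Past the threshold, 2 other probe sets differed, both lower in knockout and both of genes on chromosome 15, which carries Ppp1r1a: Pou6f1 lies 50 and Slc38a1 101 measured genes from it. Slc38a1, a neuronal glutamine transporter, fell by 1.27 on the log2 scale (SE 0.11, limma adjusted p = 0.0013) at probe set 1415903_at. Pou6f1, a POU-domain transcription factor, fell by 1.00 (SE 0.09, limma adjusted p = 0.0013) at probe set 1452844_at. Each gene had another tested probe set that did not pass: that of Slc38a1, 1454764_s_at, had a log2 change of 0.19 (SE 0.10), and that of Pou6f1, 1420749_a_at, a log2 change of -0.16 (SE 0.29). The latter was dim, at mean log2 values of 9.17 in wild type and 9.01 in knockout, so it is the weaker evidence of the 2. Both calls were lost in a variance model without an intensity trend (limma adjusted p = 0.351 for Slc38a1 and 0.503 for Pou6f1, against at most 0.0276 in every other alternative run).

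**Figure D1:**
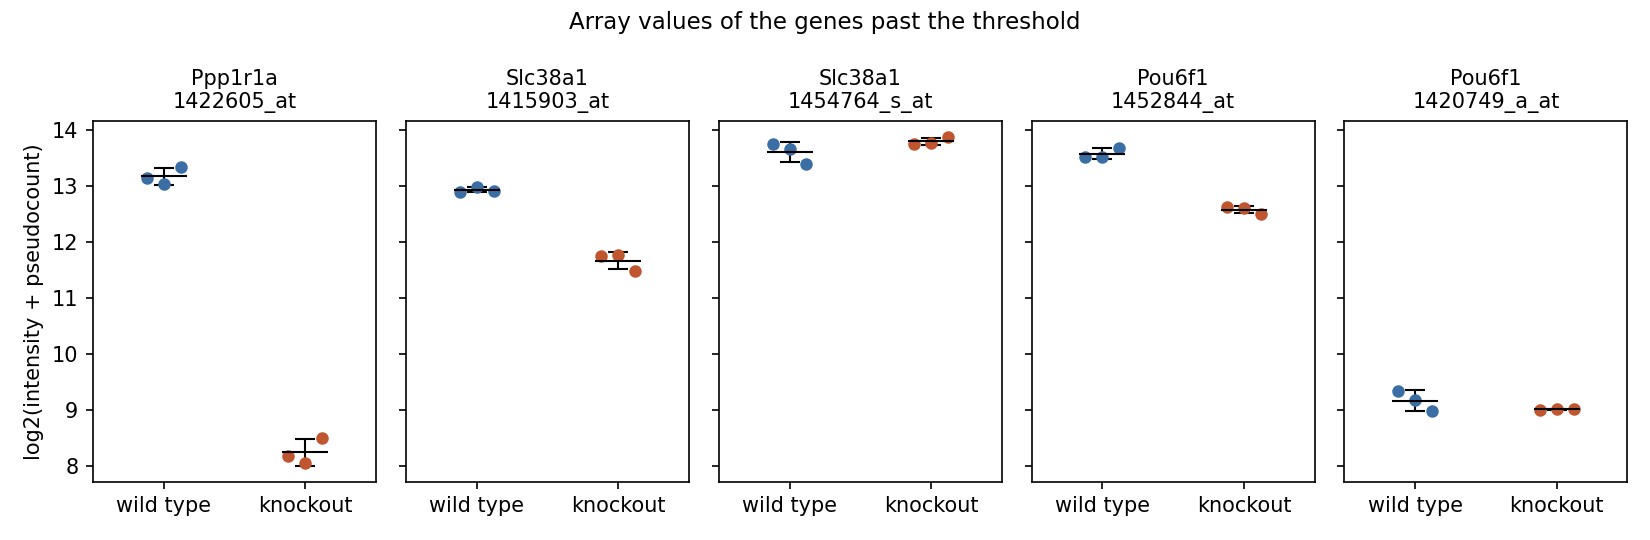
Log2(intensity + 16) on each array (points) with the mean and SD of 3 arrays per group (bars) for each tested probe set of Ppp1r1a, Slc38a1 and Pou6f1. The probe sets that passed separate the groups, and the other probe sets of Slc38a1 and Pou6f1, that of Pou6f1 being dim, do not show the same step.

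Of 26999 probe sets tested with limma, 3 were lower and 0 higher at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 586 higher and 596 lower, 1182 in all, where chance gives 1350. The groups did not overlap for 9.89% of probe sets, where chance gives 10%. The count of higher probe sets was 2 without knockout replicate 1, and 7 with the replicate number as a block, though no label pairs the samples. With alternatives chosen after seeing the data, 7 were higher and 7 lower without replicate 1 of both groups, and 1 was higher and 5 lower with the choroid plexus marker level as a covariate.

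Below the threshold, the genes ranked next among the lower ones were Smarcd1, a chromatin remodelling subunit (log2 change -0.80, limma adjusted p = 0.328), and Tmem106c (-0.84, limma adjusted p = 0.675). They were followed by Fa2h, which hydroxylates myelin lipids (-0.50), Rusc1 (-0.53), Zfp385a (-0.83), Myg1 (-0.59), Vamp2, a synaptic vesicle SNARE protein (-0.31), Erdr1 (-0.62) and Retreg2 (-0.33). Of the 12 lower genes named by the rule, 7 lie on chromosome 15, Ppp1r1a, Slc38a1 and Pou6f1 included. None of the 12 higher genes passed (lowest limma adjusted p 0.884). Their log2 changes were 0.51 for Lifr, a cytokine receptor and the 1 of them on chromosome 15, 0.70 for Gldc of the glycine cleavage system, 0.51 for Mgp, 0.37 for Ndufs8 of respiratory complex I, 0.77 for Dido1, 0.61 for Mest, 0.88 for Spop, 0.43 for Cdc26, 0.59 for Bend6, 0.86 for Eva1a, 0.49 for Rnf24 and 0.35 for Cops3. The other 5 probe sets of Ndufs8 had the same sign, and 0 of the other 2 of Spop did. The 4 other tested probe sets of Rusc1 changed by -0.17 to -0.004, and the 4 others of Dido1 by -0.49 to 0.31. The other tested probe set of Vamp2, about as bright, had a log2 change of -0.02.

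Genes next to Ppp1r1a were then compared with the rest. Ppp1r1a was the last of 490 measured genes in order on chromosome 15, so the neighbours lie on one side. Among the 25 nearest, 2 had an unadjusted p under 0.01, Zfp385a and Myg1, both lower in knockout. That is 8% against 0.963% of all other genes, an odds ratio of 8.94 (95% interval 1.01 to 36.9, two-sided Fisher's exact p = 0.0245). With the 50 nearest genes the odds ratio was 6.61 (Fisher's exact p = 0.0128), and with 100, chosen after seeing the data, 6.75 (Fisher's exact p = 0.000433). Beside these Fisher's exact tests, the camera test of a downward shift gave p = 0.185 for 25 genes, 0.00498 for 50 and 0.0227 for 100. The odds ratio was 2.66 (Fisher's exact p = 0.188) without knockout replicate 1, 21.6 without wild type replicate 2, 4.39 (p = 0.085, Fisher's exact) with array weights and 11.3 (p = 0.0935, Fisher's exact) for the 10 nearest genes.

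**Figure D2:**
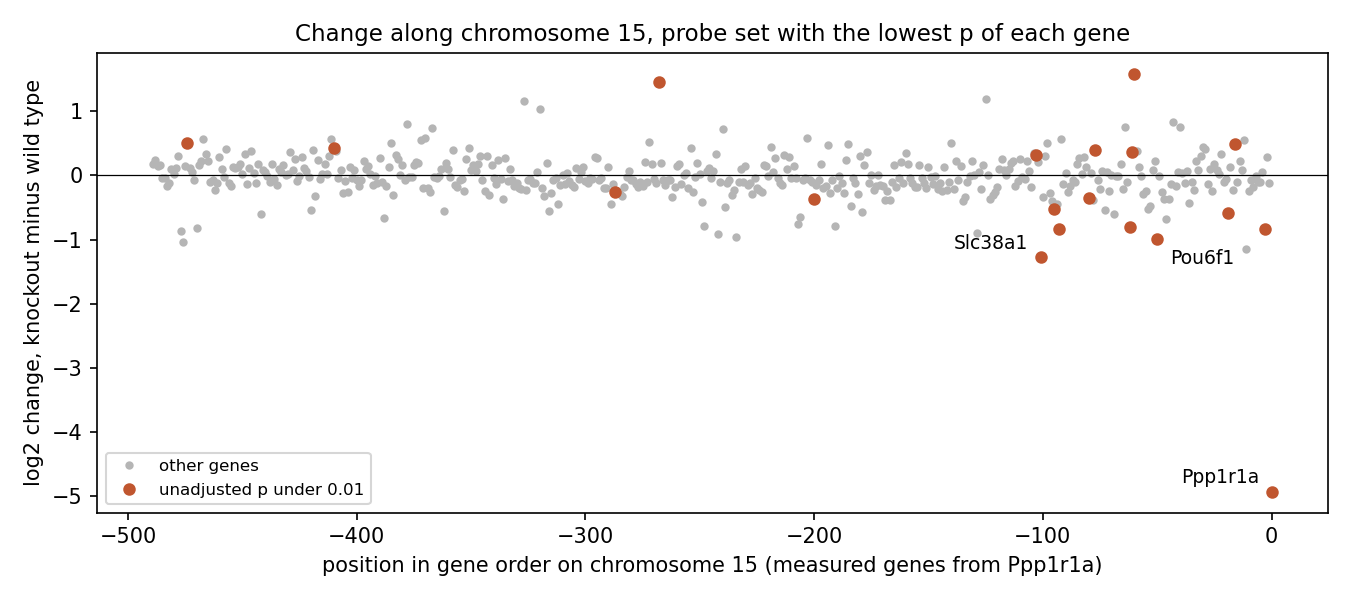
Log2 change (knockout minus wild type) of each measured gene of chromosome 15 in gene order, counted in measured genes from Ppp1r1a at 0, using the probe set with the lowest p of each gene. Genes at an unadjusted p under 0.01 are coloured, and 11 of them lie within 100 genes of Ppp1r1a besides Ppp1r1a itself.

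Markers of tissue that borders the hippocampus were the lists with the lowest p. All 13 measured meningeal and fibroblast markers had a change above 0 (median log2 change 0.37, camera adjusted p = 2.06e-06 at the preset correlation; adjusted p = 0.88 with an estimated correlation). Ogn (0.69) and Col1a2 (0.54), which encode matrix proteins, had the smallest p. Of 18 choroid plexus and ependymal markers, 15 had a change above 0 (median 0.56, camera adjusted p = 1.38e-05; adjusted p = 0.88 with an estimated correlation), with Kcnj13 at 0.77 and the tight junction gene Cldn2 at 0.72. Ttr, the transthyretin gene, had a log2 change of -0.02 at a level of 17.6 near the top of the scale. Without wild type replicate 1 the choroid plexus list was not called (median 0.17, adjusted p = 0.146), and without knockout replicate 1 its median was 0.89. Its median ran from 0.17 to 0.89 leaving out 1 array, with adjusted p up to 0.146. Without replicate 1 of both groups, chosen after seeing the data, its median was 0.49 (camera adjusted p = 2.02e-10). With the replicate number as a block it was 0.56 (camera adjusted p = 1.00e-18), though no label pairs the samples. Both p-values are at the preset correlation.

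**Figure D3:**
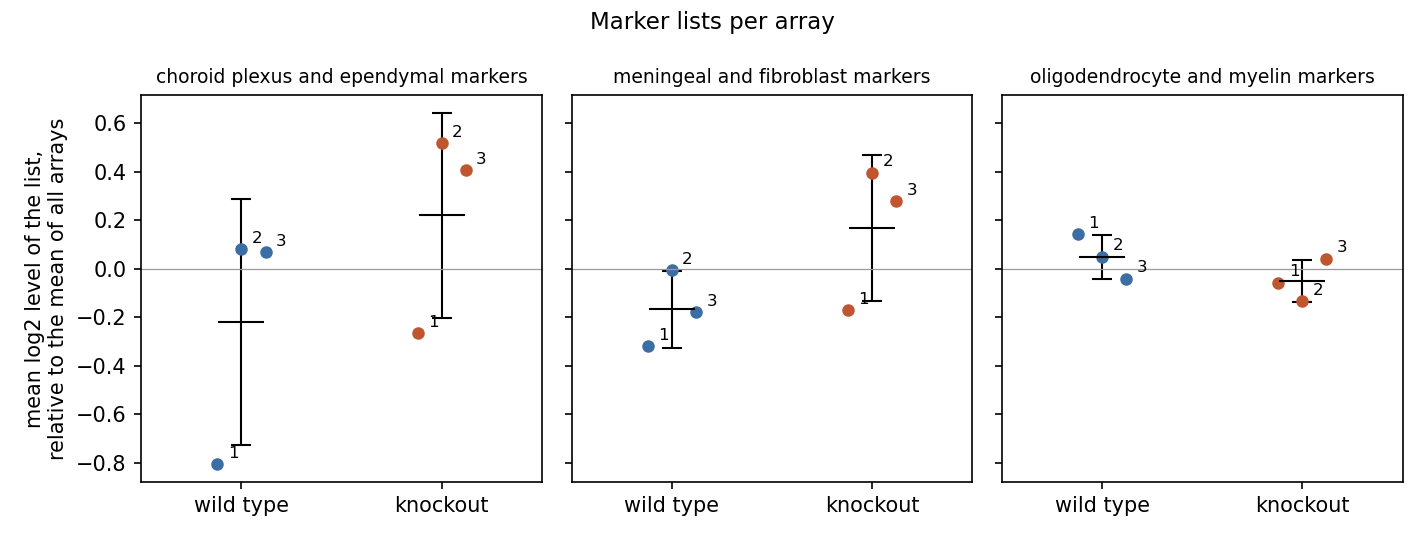
Mean log2 level of 3 marker lists on each array, relative to the mean of all 6 arrays (points, numbered by replicate), with the mean and SD of 3 arrays per group (bars). The choroid plexus level ranged from -0.81 to 0.08 in wild type and from -0.27 to 0.52 in knockout, so the groups overlap. Replicate 1 was the lowest array of both groups (-0.81 and -0.27). Each knockout array lay above the wild-type array of the same number, though no label pairs the samples.

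The mean level of the choroid plexus list was 0.44 higher in knockout on the log2 scale, beside each of the following lists. Of 18 oligodendrocyte and myelin markers, 13 had a change below 0 (median -0.12, camera adjusted p = 0.00567; adjusted p = 0.88 with an estimated correlation), and Fa2h passed when adjusted over the list alone (p = 0.00258, limma). Of 25 postsynaptic scaffold and presynaptic vesicle genes, 18 had a change below 0 (median -0.06, camera adjusted p = 0.0087; adjusted p = 0.88 with an estimated correlation), and Vamp2 passed adjusted over the list alone (p = 0.0178, limma). Of 15 glucocorticoid-responsive genes, 12 had a change above 0 (median 0.13, camera adjusted p = 0.0112; adjusted p = 0.88 with an estimated correlation), with Sgk1 at 0.50 and Zbtb16 at 0.35. Over all genes 0 list members passed in limma, and 3 passed adjusted over the list alone, the third being Alas2, a haem synthesis enzyme (log2 change 0.92, limma adjusted p = 0.027), in a red blood cell list with 3 measured members. That list had a mean log2 change of -0.08, with 1 member below 0, and its level ran from -0.92 to 0.61 among knockout arrays. By fry 0 lists were called, in one direction or mixed. These list calls changed with single arrays, 9 being called without knockout replicate 1, 8 without knockout replicate 3, 3 without wild type replicate 3 and 2 without knockout replicate 2.

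The lists closest to inhibitor-1 were not called. Camera adjusted p was 0.795 for 26 protein phosphatase 1 subunits, 0.863 for 31 cAMP and protein kinase A genes, 0.795 for 25 calcineurin and CaM kinase genes, 0.59 for 25 glutamate receptor genes, 0.764 for 11 GABA receptor genes, 0.59 for 26 voltage-gated channels and 0.762 for 30 immediate early genes. It was 0.281 for eIF2 alpha and ATF4 targets, 0.795 for heat shock genes, 0.59 for oxidative phosphorylation subunits, 0.0913 for ribosomal proteins and 0.59 for interferon and MHC class I genes. Among cell type and region lists it was 0.0607 for dentate granule neurons and for endothelial and mural cells, 0.59 for CA1 neurons, 0.795 for CA3 and CA2 neurons, 0.762 for interneurons, 0.794 for astrocytes, 0.59 for oligodendrocyte precursors, microglia, neocortex, striatum and red blood cells, 0.857 for thalamus and habenula and 0.281 for sex-linked genes. The camera direction was opposite in sign to the mean change for the red blood cell, thalamus and interneuron lists, and to the median for the cAMP list.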

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

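Alternatives chosen after seeing the data were the largest pseudocount, the neighbour threshold of 0.05, 100 neighbours, leaving out replicate 1 of both groups and the choroid plexus covariate; the cause of each change below was not tested. Ppp1r1a, Slc38a1 and Pou6f1 remained called in every alternative run except the variance model without an intensity trend, which called 1 lower probe set, Ppp1r1a. Lower counts were 7 without replicate 1 of both groups and 5 with the covariate. Higher counts were 7 without replicate 1 of both groups, 1 with the covariate, and 0 to 2 leaving out 1 array, with 2 without knockout replicate 1. The number of lists called was 0 with an estimated correlation, 3 with the covariate, which removes the choroid plexus list by construction, and 2 to 9 leaving out 1 array. The neighbour odds ratio was past Fisher's exact p of 0.05 in 16 of 22 alternatives. It was not with array weights (4.39, exact p = 0.085), without replicate 1 of both groups (2.43, exact p = 0.214), with 10 genes (11.3, exact p = 0.0935) or at a threshold of 0.05 (2.36, exact p = 0.154), and it ran from 2.66 (without knockout replicate 1, exact p = 0.188) to 21.6 leaving out 1 array. Same-numbered samples were not paired by any label, and their deviations correlated at 0.24, 0.054 and 0.0998. Wild type replicate 3 correlated best with knockout replicate 2 (0.11). Replicate 1 of either group correlated at -0.16 to -0.08 with the other numbers of the other group. It also had the lowest median intensity of its group (574 in wild type, 542 in knockout). Replicate 1 thus stood apart alike in both groups, and the labels do not say why. The replicate block gave 7 higher probe sets, 11 in all with 3 shared, and an odds ratio of 5.33 (Fisher's exact p = 0.0612). Other scalings shifted the median log2 change of the tested probe sets to -0.002 or -0.017, from 0.004. For single lists the side of the threshold was kept in 579 comparisons, gained in 24 and lost in 26, without counting a change of sign of a list called in neither; for named genes these counts were 430, 5 and 2. The median SE was 0.177 over all tested probe sets, 0.337 over the 9000 dimmest of them and 0.0969 over the 9000 brightest.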

Other observations

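Tests chosen only after the result was seen were the use of the planned neighbour test against an effect without regard to position, the comparison of probe set ratios with genes outside chromosome 15, the windows of 100 genes with and without single arrays, and all 3 tests of the choroid plexus and meningeal markers. An unnamed probe set, 1445579_at, had a log2 change of -2.09 (SE 0.27, limma adjusted p = 0.0638), passed the threshold in 8 of 19 alternatives, and was singled out after its values were seen.

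Low p genes gathered toward Ppp1r1a on chromosome 15. With the lowest p probe set of each gene, the window of 99 genes next to it held 11 at an unadjusted p under 0.01, 7 lower and 4 higher, against at most 5 in the 115 other windows. An effect of inhibitor-1 loss that ignores position is argued against as the cause of the whole gathering: leaving out each array in turn or replicate 1 of both groups, 0 of the 115 other windows held as many. The neighbour test was less stable. Its excess (25 nearest genes, Fisher's exact p = 0.0245) held in only 16 of 22 alternatives, some of which used other numbers of neighbours. Strain sequence kept around the targeted allele may change how single probe sets bind. The other probe sets moved by a median of 0.159 of the leading one's change over 7 genes, under the bound of 0.25 set beforehand. Single ratios ran from -0.41 (Sp1) to 2.83 (Gpd1), and the median was 0.097 with Slc38a1, which lies outside the window, included. But 116 genes outside chromosome 15 picked by the same p gave 0.181, so the test does not separate this from picking the lowest p. An effect of the allele that fades with distance was not shown. The 11 genes lay at a median of 61 genes from Ppp1r1a against 48 for the others, the direction set beforehand as counting against it. Random picks of 11 genes gave as low a difference of medians in a share of 0.808 of resamples (one-sided permutation p = 0.808). A median as far away is thus not rare among random picks, so the test does not exclude such an effect. The test also covered only the nearest 100 genes, and cannot see a fall over a longer range. The next windows of 100 genes on chromosome 15 held 2, 3 and 0 genes at an unadjusted p under 0.01.

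Choroid plexus and meningeal markers were higher in knockout on average. A lower share of neurons would raise all other cell types of an array alike. By the spread of list members alone, the values argue against it in these arrays. The median change of oligodendrocyte markers differed by -0.68 from that of choroid plexus markers. The upper quartiles of oligodendrocyte (0.02), precursor (0.05), astrocyte (0.11) and microglia (0.13) markers lay under the lower quartiles of choroid plexus (0.19) and meningeal (0.17) markers. Endothelial markers (0.26) were the exception. By the spread between arrays it stays open: the difference of per-array medians was -0.65, with a standard error over arrays of 0.51. List members share the same arrays, and the comparison of quartiles was chosen after the values were seen. Carry-over of bordering tissue may account for the pattern. Over 6 arrays centred on their group means the levels of both lists correlated (Pearson r = 0.866, exact permutation p = 0.0278, the smallest that 36 arrangements can give). Spearman rho was 0.829 (exact permutation p = 0.0556). But the relation rests on 2 arrays, wild type replicate 1 and knockout replicate 1, since r was 0.183 without these 2, the farthest from the median. Group means were removed first, so the correlation shows lists that vary together within groups. It does not show why knockout was higher. The range of the choroid plexus level within a group was at least 1.78 times its difference between groups, while for the meningeal list the wild-type range was 0.314 and the knockout range 0.567 against a difference of 0.335, values computed after the array levels were seen, and the 4 probe sets of Ttr, near the top of the scale at up to 17.9, changed by -0.02 to 0.14. An effect of inhibitor-1 loss cannot be told apart from carry-over. Of the 10 splits of the 6 arrays, 4 gave as large a difference of the choroid plexus level (0.44, highest other 0.67), the real one included. That met the bound first written as counting against such an effect. But the bound was wrong for 3 against 3 arrays, whose 95% interval of -0.62 to 1.499 leaves a rise open. The other splits as large all put wild type replicate 1 and knockout replicate 1, the lowest of their groups, on the same side. Their size, the interval and the range within groups thus hold the low level of these 2 arrays, and do not show that a rise is absent.

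With 3 arrays against 3 the splits are too few for a share under 0.05. The real split gave 3 probe sets past the threshold against at most 0 in the others (1 of 10 splits as large), and 2 low p genes among the 25 neighbours against at most 0 (1 of 10). It called 5 gene lists, where the highest other split called 10 and 6 of the 10 gave as many, so the preset correlation calls lists under other groupings of these arrays too.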
